A study of Oryza sativa with 81 samples.

How the data were processed

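Total RNA of 9 rice lines (Oryza sativa) was sequenced in 3 tissues, with 3 libraries per line and tissue. Per the labels, the plants grew in an experimental field, and libraries were made from ribosomal RNA-depleted total RNA by a stranded method. Reads were aligned with HISAT2, per the submitters' processing notes. Its version, the counting tool, the genome build and the annotation are not given in the sources used here. The authors deposited raw read counts per gene model, which are whole numbers with totals that differ between libraries. They also deposited FPKM values (fragments scaled by gene length and library total), and 100% of these lay within 1% of the count divided by a gene length and the library total. The FPKM values add only a length, found for 29123 gene models (median 1439 bases, 36.1% of them multiples of 3), so they were not tested.

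The count table held 38714 gene models, 452 of which had no count in any library, and every column was matched to 1 library by its title. Groups were taken from the labels for line and tissue, giving 27 groups of 3. Totals ran from 29054241 to 45765805 counts, and 3 counts over a group was taken as the floor of a group at 0. Intervals and floors cover counting error only. All 81 pairs of libraries within a group differed by far more than sampling noise (chi-square per degree of freedom 5.83 to 307, median 31.5), so each library was counted as its own replicate. None of the identifiers was found in the gene name table used here (39387 genes, another assembly). Identifiers are therefore printed as deposited, with at most 2 higher and 2 lower genes in each comparison, and the gene lists and cell type markers drawn up beforehand could not be read. Because the counting method is not stated, genes that share reads with a near-identical copy are uncertain. Gene positions were not used beyond the order of the identifiers.

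Counts were analysed in R 4.3.3 with edgeR 4.0.16. Within each tissue, genes were kept by filterByExpr (21813 in young seedlings, 24748 in young panicles, 25336 in filling panicles), libraries were scaled by the trimmed mean of M-values (TMM), and 1 quasi-likelihood model was fitted to all 27 libraries with a mean for each line. Tissues were compared in 1 model over the 81 libraries and 27316 genes. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A hybrid was tested against the arithmetic mean of its parents through an offset for each gene, with parental weights rounded to steps of 0.1. Genes beyond both parents had to differ from each parent in the same direction. The mean deviation is the average over the 5 crosses, and the interaction compares the log2 effect of R998 against R308 between WFB and RFB crosses. All p-values of these tests are two-sided. CPM values are counts scaled by TMM-adjusted library sizes. Sets of genes were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and with fry. Fisher's exact tests and the library summaries were made in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, or in R, and figures with matplotlib 3.10.9.

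The groups, comparisons, tests, listed alternatives and the rule for naming genes were chosen before the data were examined. That rule took, among genes with adjusted p under 0.05 and at least 5 CPM in the higher group, those with the largest change in each direction between tissues, between parents and in the mean deviation, the gene farthest beyond both parents in each cross, and those with the largest interaction. For parents and for genes beyond both parents, the libraries of the groups could not overlap, and mean deviations had to share a sign in 5 of 5 crosses. The rule passed over genes without a symbol. As no gene had one, this part could not be kept. The tissue-enriched sets (at least 8-fold in the 4 parents), the identifier blocks, the genes marking 1 parent, the left-out block 00 and the left-out pair of libraries were chosen after seeing the data.

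The tests of single genes were tried on simulated counts with the real library sizes, with 200 genes changed by known folds. Hybrids were set at the mid-parent of the real parental means. For the other tests all groups shared 1 mean per gene. Parents were simulated for WFB against R998 only, genes beyond both parents for WY998 only, and tissues for filling panicles against young seedlings only. Set tests, Fisher's tests and neighbour draws were not simulated. No simulated library stood apart, so false calls in the real data may be more frequent. For the hybrids against mid-parent, 84% to 93% of the 2-fold changes were recovered with 5 to 14 false calls. The interaction recovered 63% of the 2-fold changes in young seedlings, 68% in young panicles and 50% in filling panicles. With a geometric mid-parent for WY998, 693, 971 and 589 genes were called falsely in the 3 tissues. Alternatives were DESeq2 1.42.0 in place of edgeR, its size factors in place of TMM, no filter on low counts, only the lines compared in the fit, the replicate number as a block, a geometric mid-parent and each library left out. For the splits, libraries were reassigned 20 times for each result, which with the real assignment makes 21.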

Results

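RNA was sequenced from 9 rice lines in a study concerned with forecasting heterosis, the advantage of a hybrid over its parents. The lines were 4 parents, named R998, R308, RFB and WFB, and 5 first-generation hybrids. WY998 and WY308 were crosses of WFB with R998 and R308. RY998 and RY308 were crosses of RFB with the same 2 lines, and WR was the cross of WFB with RFB. Field-grown plants were sampled as young seedlings, young panicles and filling panicles, with 3 libraries for each line in each tissue and 81 in all. A library held 29054241 to 45765805 counts, and 23708 to 37377 of the 38714 gene models had at least 1 count in a library. The labels do not state that replicates were separate plants or plots, so every p-value covers only the spread between these libraries. Gene models carry identifiers whose first 2 digits run from 00 to 12, called identifier blocks here. None of the identifiers was paired with a gene name, so genes are given by identifier and what they encode is not stated.

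Libraries of a line were highly correlated within every tissue, but some correlated as highly with a library of another line. The mean correlation of a library with the other libraries of its line, across genes, was 0.963 to 0.989 in young seedlings, 0.979 to 0.993 in young panicles and 0.922 to 0.990 in filling panicles. The lowest value belonged to R998 replicate 9, which stood apart from the other filling panicle libraries of R998. Its highest correlation with a library of another line was 0.951. In filling panicles WY308 replicates 7, 8 and 9 had means of 0.940, 0.965 and 0.944 within their line. Their highest values with another line were 0.967, 0.974 and 0.953. WY998 replicate 5 in young panicles had 0.987 and 0.993. Identifier block 00, a group of 114 gene models, took 51.9% ± 3.15 of the counts in young seedlings (SD, n = 27), 5.17% ± 0.615 in young panicles and 8.01% ± 1.32 in filling panicles. The 10 most abundant gene models took 53.9% ± 3.29 of the counts in young seedlings, 5.17% ± 0.634 in young panicles and 18.7% ± 3.31 in filling panicles. A pair of filling panicle libraries had counts on many more gene models than the rest. R308 replicate 9 had counts on 37377 gene models and RY308 replicate 8 on 34375, against at most 29270 in the other 79 libraries. On 6501 gene models with at most 1 count over the other 25 filling panicle libraries, these 2 libraries had counts on 5619 and 3557, which made up 0.184% and 0.0302% of their counts.

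**Figure D1:**
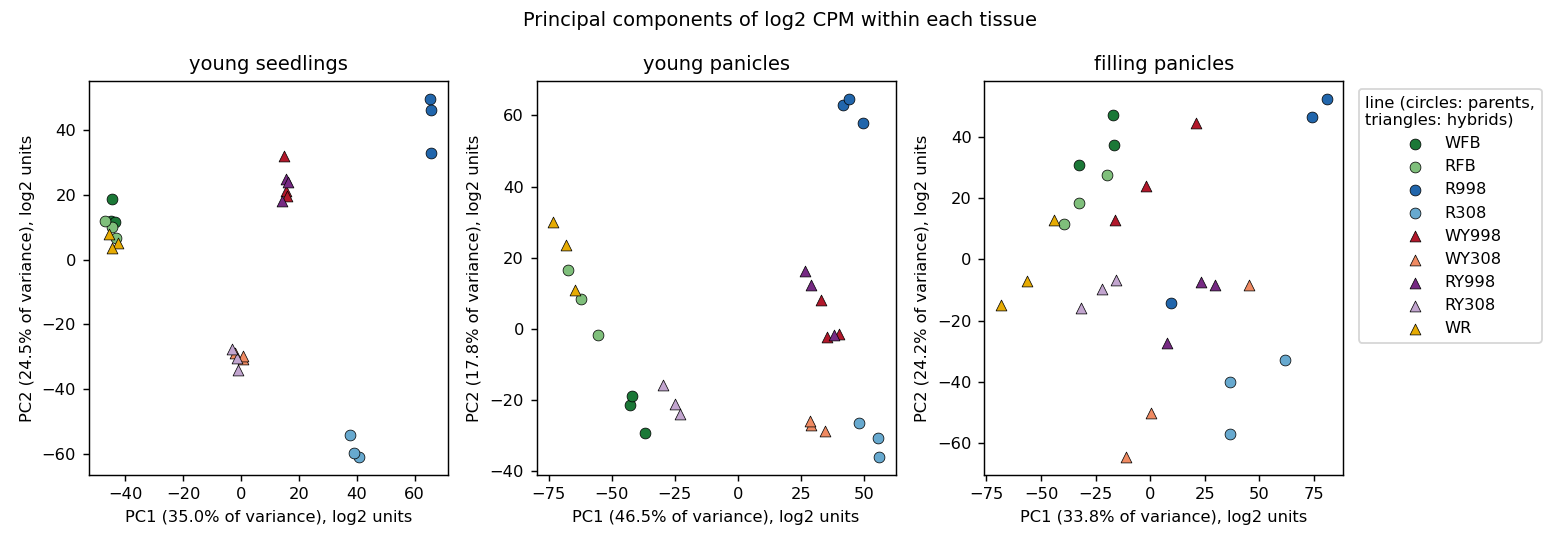
Principal components of log2 CPM (counts scaled by library size) within each tissue, with PC1 on the horizontal and PC2 on the vertical axis. Each point is a library, circles are parents and triangles are hybrids. PC1 held 35.0% of the variance in young seedlings, 46.5% in young panicles and 33.8% in filling panicles.

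Genes present in a single parent were followed into the hybrids as a check of the labelled crosses. These genes had at least 5 CPM in 1 parent and under 0.1 CPM in the other 3. There were 3 to 53 of them for R998 or R308 in a tissue, 1 for WFB in young panicles, and none otherwise for WFB or RFB. In the 36 libraries of the 4 hybrids with R998 or R308 as a parent, genes of the one in the cross had a median level of at least 0.351 of that parent, and genes of the other a median of at most 0.0138. With a limit of 20 CPM the latter reached 0.182 in WY998 replicate 6, over 2 genes of R308. The WFB gene was lowest at 0.248 of WFB, in WY998 replicate 6, among the libraries of WY998 and WY308.

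Young panicles were set against young seedlings over all 9 lines to show what separates the tissues. OsR498G0510793900.01 reached 1213 ± 544 CPM in young panicles (SD, n = 27) and 0.0112 ± 0.0311 CPM in young seedlings. OsR498G0100558200.01 reached 933 ± 370 against 0.0103 ± 0.0253 CPM. In the other direction, OsR498G0102749300.01 lay at 0.00702 ± 0.0177 CPM in young panicles and 850 ± 247 CPM in young seedlings, and OsR498G1221717500.01 at 0.0111 ± 0.0350 against 677 ± 220 CPM. Of 27316 genes tested, 12597 were higher and 10928 lower in young panicles (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Changes of at least 2-fold were found for 8398 higher and 5934 lower genes, and of at least 8-fold for 4322 and 1912.

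Filling panicles were set against young seedlings in the same way. OsR498G0102044500.01 reached 30789 ± 10974 CPM in filling panicles (SD, n = 27) and 0.00827 ± 0.0179 CPM in young seedlings. OsR498G0713719900.01 reached 13965 ± 7221 CPM and had no count in the 27 seedling libraries. OsR498G0203308700.01 fell to 0.0475 ± 0.126 CPM from 135 ± 70.2 CPM in seedlings, and OsR498G1120591500.01 to 0.0947 ± 0.226 from 67.4 ± 48.6 CPM. In all, 12772 genes were higher and 10923 lower in filling panicles, of which 8162 and 5818 changed by at least 2-fold and 4119 and 1434 by at least 8-fold. The median log2 difference over all tested genes was 0.16, and 0.26 with DESeq2 size factors, so small changes in this comparison depend on the scaling.

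Between the panicle stages, OsR498G0713719900.01 rose from 0.768 ± 3.97 CPM in young panicles to 13965 ± 7221 CPM in filling panicles (SD, n = 27). OsR498G0306248900.01 rose from 0.450 ± 2.32 to 11463 ± 3160 CPM. OsR498G1120412300.01 was at 526 ± 253 CPM in young panicles and 0.0322 ± 0.0873 CPM in filling panicles, and OsR498G1018151400.01 at 450 ± 144 against 0.0364 ± 0.0722 CPM. The young panicle levels of both rising genes came almost wholly from 1 library, RY308 replicate 4. It held OsR498G0713719900.01 at 28.1 CPM and OsR498G0306248900.01 at 16.4 CPM, while the other 26 libraries did not exceed 0.0300 and 0.0505 CPM. OsR498G0102044500.01 was at 47.9 CPM in that library and at most 0.343 CPM in the others. Of 27316 genes, 11677 were higher and 11836 lower in filling panicles, 5409 and 5888 of them by at least 2-fold and 2148 and 1734 by at least 8-fold. The balance turned with the scaling, to 12082 higher and 11445 lower with DESeq2 size factors and to 12418 and 11117 without block 00.

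Sets of tissue-enriched genes were drawn from the 4 parents, as genes at least 8-fold higher in 1 tissue than in both others. The 900 seedling-enriched genes took 59.3% ± 2.98 of the counts of young seedlings (SD, n = 27), 3.93% ± 0.586 in young panicles and 7.25% ± 1.34 in filling panicles. The 1297 genes enriched in young panicles took 9.17% ± 0.560 of the counts there, 0.0891% ± 0.0216 in seedlings and 0.358% ± 0.0853 in filling panicles. The 1284 genes enriched in filling panicles took 28.7% ± 5.87 of the counts there, 0.110% ± 0.0132 in seedlings and 0.239% ± 0.0286 in young panicles. Because the parents' own libraries chose the sets, these shares are not independent evidence of the tissue differences.

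The parents of each cross were compared to show how far their counted expression levels differed. All lines were counted on the same gene models. No count in a parent therefore does not show whether the gene was silent or its reads could not be counted. In young seedlings, OsR498G1119610000.01 was at 28.6 ± 2.44 CPM in WFB and 41.4 ± 4.02 CPM in RFB (SD, n = 3), with no count in R998. Against a floor of 3 counts over the 3 libraries of R998, this was at least 869.5-fold higher in WFB. OsR498G0305704200.01 was at 76.9 ± 1.24 CPM in WFB and 75.9 ± 3.68 CPM in RFB, with no count in R308. R998 held OsR498G0204315700.01 at 429 ± 107 CPM, where WFB had 0.00972 ± 0.0168 CPM from a single count, and OsR498G0612483700.01 at 51.1 ± 4.41 CPM, where RFB had no count. R308 held OsR498G0612514800.01 at 99.5 ± 14.1 CPM, with no count in WFB, and OsR498G0815371500.01 at 58.1 ± 18.3 CPM, with no count in RFB. Of 21813 genes tested, 4532 differed between WFB and R998 (2335 higher in WFB), 4385 between WFB and R308 (2276 higher in WFB), 4331 between RFB and R998 (2275 higher in RFB) and 4129 between RFB and R308 (2170 higher in RFB). Against R998 the balance turned with DESeq2 size factors, to 2207 higher and 2292 lower in WFB and 2086 higher and 2229 lower in RFB, and it turned without block 00 as well.

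In young panicles, OsR498G0203991200.01 was at 15.3 ± 0.871 CPM in WFB and 16.0 ± 0.640 CPM in RFB (SD, n = 3) and had no count in R998, at least 550-fold lower than in WFB. OsR498G0101198100.01 was at 44.0 ± 7.15 CPM in WFB and 43.7 ± 4.10 CPM in RFB, with no count in R308. R998 held OsR498G0612514800.01 at 76.2 ± 11.5 CPM and OsR498G0611753600.01 at 33.1 ± 2.51 CPM, the first with no count in WFB and the second with none in RFB. R308 held OsR498G0203221200.01 at 112 ± 3.96 CPM, with no count in WFB, and OsR498G1119903200.01 at 64.3 ± 2.43 CPM, with no count in RFB. Of 24748 genes tested, 10827 differed between WFB and R998 (5462 higher in WFB), 9077 between WFB and R308 (4576 higher in WFB), 10347 between RFB and R998 (5158 higher in RFB) and 12267 between RFB and R308 (6302 higher in RFB). With DESeq2 size factors 4237 were higher and 4751 lower in WFB than in R308, and 5772 higher and 6290 lower in RFB.

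In filling panicles, OsR498G0714047000.01 was at 44.8 ± 1.97 CPM in WFB and 58.8 ± 8.79 CPM in RFB (SD, n = 3) and had no count in R998, at least 1612.96-fold lower than in WFB. OsR498G0816020800.01 was at 26.9 ± 1.93 CPM in WFB and 24 ± 1.23 CPM in RFB, with no count in R308. R998 held OsR498G0204305500.01 at 59.4 ± 12.7 CPM, with no count in WFB, and OsR498G0713921000.01 at 43.2 ± 4.06 CPM, with no count in RFB. R308 held OsR498G0102662000.01 at 15 ± 1.99 CPM, with no count in WFB, and OsR498G0714097600.01 at 7.82 ± 2.70 CPM, where RFB had 0.0103 ± 0.0179 CPM from a single count. Of 25336 genes tested, 5404 differed between WFB and R998 (2672 higher in WFB), 8651 between WFB and R308 (4722 higher in WFB), 5260 between RFB and R998 (2580 higher in RFB) and 7210 between RFB and R308 (3796 higher in RFB). Against R308 the balance turned with DESeq2 size factors, to 3889 higher and 4484 lower in WFB and 3227 higher and 3824 lower in RFB, and without block 00, to 4124 and 4293 in WFB and 3387 and 3660 in RFB. For RFB and R998 it turned to 2656 higher and 2545 lower with DESeq2 size factors. Among 20594 genes tested in every tissue, 1236 differed with the same sign in all 3 tissues between WFB and R998, 1371 between WFB and R308, 1292 between RFB and R998 and 1279 between RFB and R308.

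WFB and RFB, the parents of WR, differed in fewer genes than the other pairs in every tissue. OsR498G0611623000.01 was at 23.8 ± 1.54 CPM in WFB seedlings and 13.9 ± 0.684 CPM in WFB young panicles (SD, n = 3), and RFB had no count in either. Against a floor of 3 counts over the 3 libraries, it was at least 842-fold and at least 504-fold higher in WFB. RFB seedlings held OsR498G0714841800.01 at 17 ± 0.260 CPM, at least 556-fold above WFB, and RFB young panicles held OsR498G0204888400.01 at 8.40 ± 0.653 CPM, at least 322-fold above WFB. In filling panicles OsR498G0408431100.01 was at 9.42 ± 0.696 CPM in WFB, at least 293-fold above RFB. There OsR498G0613162800.01 was at 7.18 ± 0.560 CPM in RFB and 0.00835 ± 0.0145 CPM in WFB from 1 count, a ratio of 861 with a counting interval from 154 to 33997. In young seedlings 393 genes differed (182 higher in WFB), in young panicles 5330 (2755 higher in WFB) and in filling panicles 180 (99 higher in WFB), and 83 of 20594 genes differed with the same sign in all tissues. The seedling count was 258 without WFB replicate 1, and the young panicle count was 3015 without RFB replicate 5, 3506 without RFB replicate 6 and 3306 without WFB replicate 4.

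The genes that separated WFB from RFB were unevenly spread over the identifier blocks. In young seedlings 141 of 1804 tested genes of block 06 differed (7.82%), against 252 of 20009 in the other blocks (1.26%; Fisher's exact test, two-sided, adjusted p = 8.12e-54 over 3 tissues). In filling panicles it was 88 of 2053 (4.29%) against 92 of 23283 (0.395%, adjusted p = 1.31e-47). Young panicles had 566 of 2022 (28%) against 4764 of 22726 (21.0%, adjusted p = 8.11e-13). The block was singled out after the counts by block had been seen, and genes are not independent of each other.

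**Figure D2:**
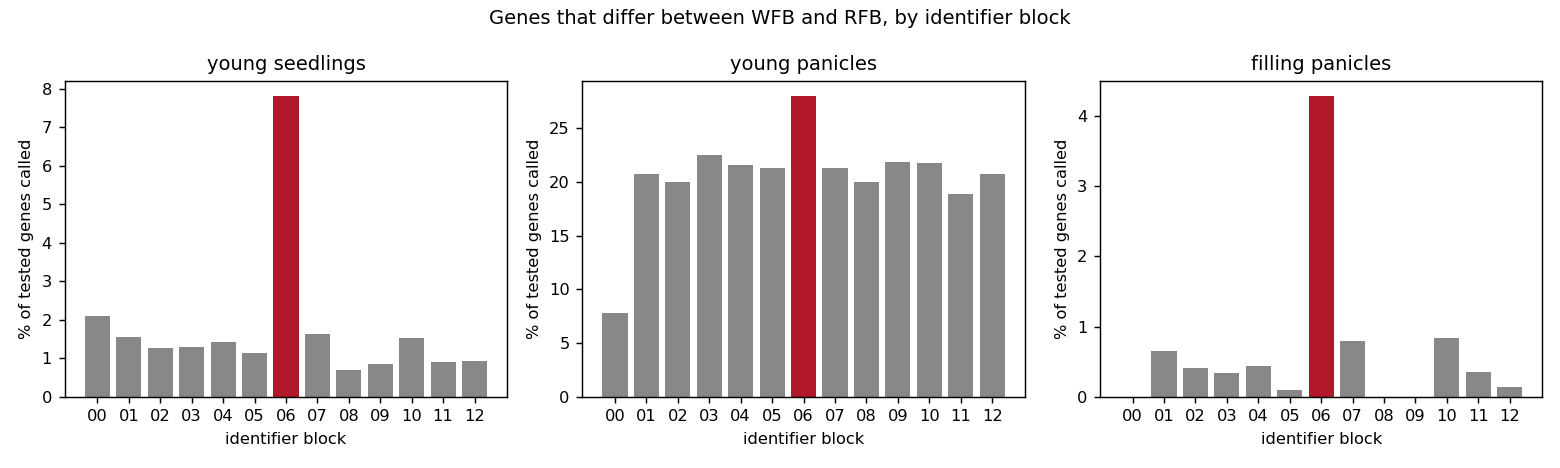
Percentage of tested genes that differed between WFB and RFB (vertical axis) in each identifier block (horizontal axis), for the 3 tissues, with block 06 in red. In young seedlings block 06 reached 7.82%, while the other numbered blocks from 01 to 12 lay between 0.703% and 1.64%.

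Hybrids were set against their own parents to find expression beyond the parental range. OsR498G0611894900.01, in block 06, lay farthest below both parents in each of the 4 hybrids that have R998 or R308 as a parent, in young seedlings and in young panicles. Its seedling level was 0.169 ± 0.0248 CPM in WY998, 0.143 ± 0.118 in WY308, 0.0993 ± 0.0459 in RY998 and 0.114 ± 0.118 in RY308 (SD, n = 3). The parents had 8.39 ± 0.710 (WFB), 8.93 ± 2.03 (RFB), 12.7 ± 4.12 (R998) and 9.95 ± 1.44 CPM (R308), and WR had 12.5 ± 3.91 CPM. In young panicles it lay at 0.505 to 1.03 CPM in these 4 hybrids, against 27.7 to 44.3 CPM in the parents and 42.6 ± 3.63 CPM in WR. In filling panicles it was at 0.366 to 0.638 CPM in the same hybrids, against 28.5 to 76.2 CPM in the parents and 23.7 ± 1.1 CPM in WR, and lay farthest below both parents in each of them but RY998. RY998 filling panicles held OsR498G0612408600.01 at 0.0451 ± 0.0302 CPM, against 19.0 ± 2.08 CPM in RFB and 12.9 ± 2.46 CPM in R998.

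**Figure D3:**
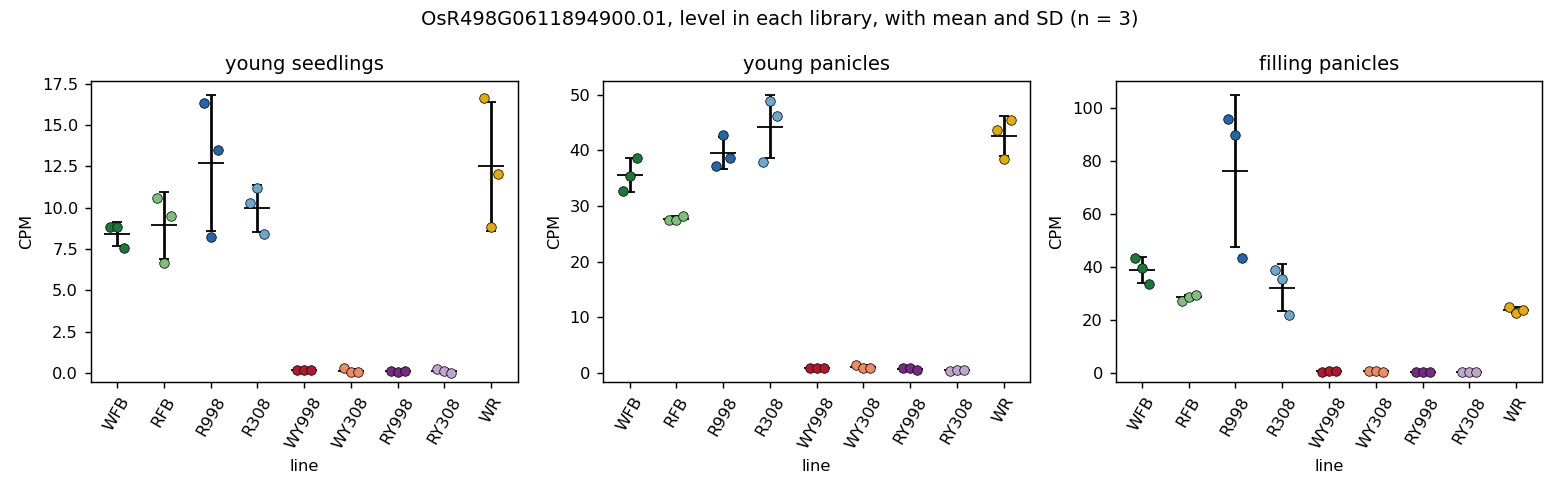
Level of OsR498G0611894900.01 in CPM (vertical axis) for the 9 lines (horizontal axis) in each tissue. Points are libraries, and bars give the mean and SD (n = 3). WY998, WY308, RY998 and RY308 lay at or below 1.03 CPM on average in every tissue, and the parents and WR at or above 8.39 CPM.

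Other genes lay above both parents. OsR498G0612192000.01 was at 27 ± 3.26 CPM in WY998 seedlings (SD, n = 3), against 8.82 ± 0.185 in WFB and 11.8 ± 2.22 in R998. OsR498G0022212200.01, in block 00, was at 84.4 ± 5.70 CPM in RY308 seedlings, against 27.6 ± 5.06 in RFB and 25.3 ± 1.53 in R308. The same gene was at 190 ± 1.39 CPM in WY998 filling panicles, against 72.9 ± 12.6 in WFB and 49.9 ± 6.19 in R998. RY998 filling panicles held OsR498G0101835100.01 at 6.05 ± 1.48 CPM, against 0.0832 ± 0.115 in RFB and 0.169 ± 0.0661 in R998, and RY308 filling panicles held OsR498G0612770700.01 at 10.1 ± 1.5 CPM, against 2.62 ± 0.543 in RFB and 2.58 ± 0.278 in R308. OsR498G1220845700.01 was at 5.61 ± 1.28 CPM in RY308 young panicles, against 1.14 ± 0.301 in RFB and 0.864 ± 0.129 in R308. Several leading genes varied widely between libraries of the hybrid. OsR498G0307156500.01 was at 30.0 ± 27.2 CPM in WY998 young panicles, OsR498G0407971100.01 at 5.15 ± 7.69 in WY308 and OsR498G0408529500.01 at 5.75 ± 5.05 in RY998 young panicles, OsR498G0204209400.01 at 11.3 ± 6.07 in WY308 seedlings, OsR498G0714192300.01 at 8.53 ± 4.86 in WY308 filling panicles, and OsR498G1019172000.01 at 5.74 ± 3.54 in RY998 seedlings. Of these 6 calls 5 depended on single libraries. The edgeR adjusted p of OsR498G1019172000.01 rose to between 0.0682 and 0.136 without R998 replicate 1 or 3, RFB replicate 1, 2 or 3, or RY998 replicate 2 or 3. OsR498G0204209400.01 had 0.0634 to 0.134 without WFB replicate 1 or 2, or WY308 replicate 1 or 3, and OsR498G0307156500.01 had 0.105 to 0.121 without WFB replicate 4 or 5, or WY998 replicate 6. The adjusted p was 0.371 for OsR498G0407971100.01 without WY308 replicate 6 and 0.0514 for OsR498G0408529500.01 without RY998 replicate 5.

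For WR, whose parents were the most alike, OsR498G0203360700.01 lay at 1.41 ± 0.348 CPM in seedlings (SD, n = 3), below WFB at 9.69 ± 3.56 and RFB at 7.75 ± 1.18. OsR498G0917872200.01 was at 5.27 ± 5.95 CPM in WR seedlings, against 0.0301 ± 0.0272 in WFB and 0.0588 ± 0.0627 in RFB. In WR young panicles OsR498G0407591100.01 was at 10.5 ± 3.74 CPM, against 2.66 ± 1.22 in WFB and 2.97 ± 0.343 in RFB, and OsR498G0204006100.01 at 17.6 ± 9.08, against 131 ± 38.0 and 54.9 ± 9.42. In WR filling panicles OsR498G0511123500.01 was at 20.2 ± 1.85 CPM, against 6.54 ± 1.28 in WFB and 5.55 ± 0.686 in RFB, and OsR498G0407779200.01 at 0.0189 ± 0.0327, against 4.83 ± 2.79 and 5.72 ± 3.07. The edgeR adjusted p of OsR498G0204006100.01 was 0.0531 to 0.203 without RFB replicate 4, 5 or 6, WFB replicate 5, or WR replicate 5 or 6. That of OsR498G0407591100.01 was 0.0932 to 0.176 without RFB replicate 4, 5 or 6, or WR replicate 5, and that of OsR498G0407779200.01 0.0649 to 0.242 without any 1 of the 9 libraries except RFB replicate 7.

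Summed over the 5 crosses, 2077 gene calls in young seedlings lay beyond both parents, 930 above and 1147 below. Young panicles gave 2887 (1795 above, 1092 below) and filling panicles 1817 (779 above, 1038 below). Seedling calls numbered 1316 in WR, 395 in RY998, 239 in RY308, 64 in WY308 and 63 in WY998. In young panicles they numbered 1299 in RY998, 726 in WY998, 684 in RY308 and 52 in WY308, and WR had 47 above and 79 below. In filling panicles RY998 had 1561, RY308 134, WY308 75, WY998 24 and WR 23. A call needed an adjusted p under 0.05 against each parent in the same direction. The seedling sum was 1366 without RFB replicate 2 and 1382 without RFB replicate 3, and the young panicle sum was 1679 without R998 replicate 4.

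Each hybrid was also tested against its mid-parent, the arithmetic mean of both parents, which additive expression would give. In young seedlings WR deviated in 3324 genes (1646 above, 1678 below), RY998 in 916 (399 above, 517 below), RY308 in 518 (258 above, 260 below), WY308 in 187 (45 above, 142 below) and WY998 in 61 (21 above, 40 below). Against a geometric mid-parent, which lies below the arithmetic one wherever the parents differ, the split was 795 above and 138 below for WY998, 773 and 235 for WY308, 1392 and 637 for RY998 and 1035 and 341 for RY308. DESeq2 called 204 genes for WY998, 457 for WY308 and 903 for RY308, and fits to the compared lines alone gave 16 for WY998, 361 for WY308 and 2208 for WR. The near-even splits of WR and RY308 turned with DESeq2 size factors, to 1684 above and 1621 below and 268 and 256. The WR count was 2135 without WR replicate 3. For RY998 it was 1475 without R998 replicate 2, 604 without RFB replicate 2 and 479, 360 and 391 without RY998 replicates 1, 2 and 3. The RY308 count was 319 without R308 replicate 1, 334 without RFB replicate 2 and 212, 173 and 160 without RY308 replicates 1, 2 and 3. For WY308 it was 119 without WFB replicate 1 and 47 without WY308 replicate 2 or replicate 3, and for WY998 it was 115 without R998 replicate 2 and 26, 28 and 100 without WY998 replicates 1, 2 and 3.

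In young panicles RY998 deviated from mid-parent in 6028 genes (3105 above, 2923 below), WR in 5309 (1940 above, 3369 below), RY308 in 3792 (1540 above, 2252 below), WY998 in 3381 (1810 above, 1571 below) and WY308 in 1331 (703 above, 628 below). The geometric mid-parent gave 3082 above and 1365 below for WY998, 1751 and 523 for WY308, 4288 and 2624 for RY998 and 2672 and 1969 for RY308. Without block 00 the split was 1683 above and 1700 below for WY998 and 2976 and 3043 for RY998. RY308 replicate 4, the library with filling panicle transcripts, and replicate 5 mattered for RY308, which had 2372 genes without the first and 2249 without the second. The RY998 count was 2843 without RY998 replicate 5, and the WY998 count 1767 without WY998 replicate 5. It was 735 for WY308 without WY308 replicate 5, and for WR 3433 without WR replicate 5 and 2033 without WR replicate 6.

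In filling panicles RY998 deviated in 3216 genes (1320 above, 1896 below), WY308 in 1648 (652 above, 996 below), RY308 in 1557 (533 above, 1024 below), WR in 291 (125 above, 166 below) and WY998 in 36 (11 above, 25 below). The geometric mid-parent gave 610 above and 81 below for WY998, 1409 and 814 for WY308, 2092 and 1853 for RY998 and 1226 and 960 for RY308. Leaving out block 00 gave 5 above and 20 below for WY998. The order of the hybrids by count depended on the fit. With only the compared lines fitted WR had 3551 genes, RY998 2318, RY308 1879, WY308 218 and WY998 13, and DESeq2 called 1059 for WR and 168 for WY998. Without R308 replicate 9 and RY308 replicate 8, the libraries with counts on the most gene models, RY308 had 826 genes, WR 171 and WY308 935. The RY998 count was 1857 without RY998 replicate 7, and the RY308 count 622 without RY308 replicate 7 and 764 without RY308 replicate 8. For WY308 it was 1067 without R308 replicate 9, 869 without WFB replicate 7, 2708 without WY308 replicate 7 and 599 without WY308 replicate 9. For WY998 it was 86 without R998 replicate 9, 23 without WFB replicate 8, 17 without WY998 replicate 7 and 15 without WY998 replicate 8. The WR count was 115, 75 and 20 without RFB replicates 7, 8 and 9, 12, 77 and 185 without WFB replicates 7, 8 and 9, and 4, 153 and 2 without WR replicates 7, 8 and 9.

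**Figure D4:**
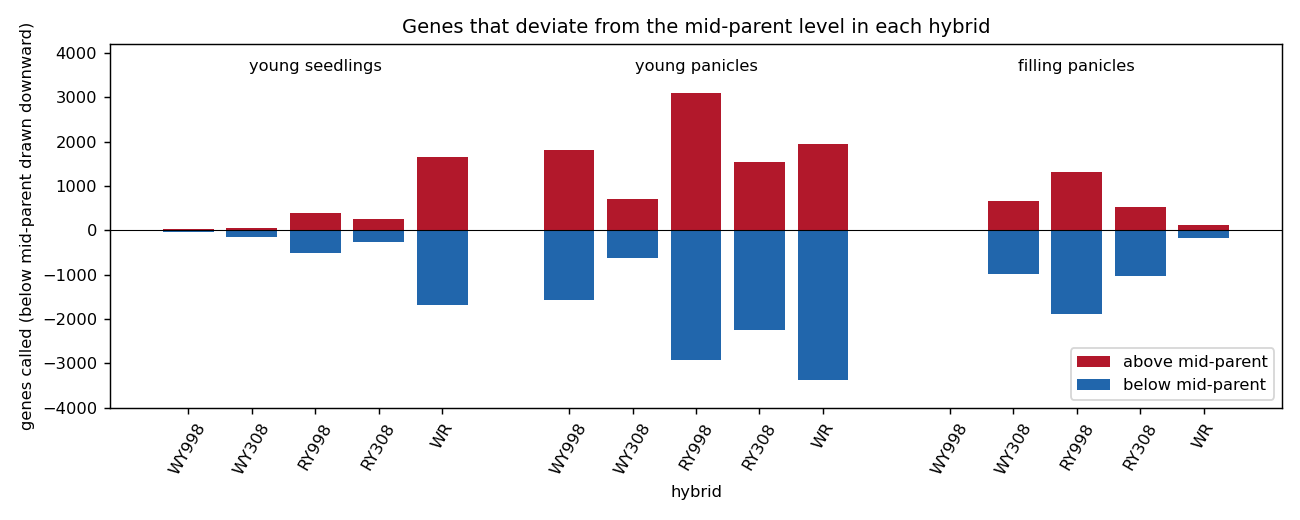
Number of genes above (red, upward) and below (blue, downward) the mid-parent level (vertical axis) in each hybrid (horizontal axis), for the 3 tissues. RY998 in young panicles had the most calls, 3105 above and 2923 below.

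The mean deviation over the 5 crosses showed which genes departed from mid-parent on average. In young seedlings OsR498G1019203700.01 lay below mid-parent (log2 change -2.27, SE 0.217, adjusted p = 2.32e-07), with 0.720 to 2.14 CPM in the hybrids and 2.40 to 8.22 CPM in the parents. OsR498G0202926900.01 also lay below (log2 change -1.92, SE 0.150, adjusted p = 1.21e-08). OsR498G0917871200.01 (log2 change 2.24, SE 0.590, adjusted p = 0.00988) and OsR498G0510710800.01 (2.16, SE 0.527, adjusted p = 0.00581) lay above. The first of these was uneven, from 0.713 ± 0.374 CPM in WY998 to 31.0 ± 33.9 CPM in WR (SD, n = 3). Of 21813 genes 1924 were above and 2340 below, with a median size of 0.30 on the log2 scale over the 4264 called genes, 224 of which deviated by at least 2-fold. Against geometric mid-parents the split was 3161 above and 2226 below. Of the called genes 3806 shared a sign in 5 of 5 crosses, and the count was 2797 without WR. The crosses share parents, here and in the other tissues, so their signs are not independent. The third principal component (11.2% of the variance in young seedlings) separated all parent libraries, at 1.73 to 37.1, from all hybrid libraries, at -0.899 or lower. The cause of that separation was not tested.

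In young panicles OsR498G0612784300.01, in block 06, lay below mid-parent (log2 change -3.19, SE 0.0836, adjusted p = 9.70e-18). It was at 16.7 to 19.1 CPM in WY998, WY308, RY998 and RY308, 272 ± 49.2 CPM in WR (SD, n = 3) and 247 to 305 CPM in the parents. OsR498G0714461100.01 lay below as well (log2 change -3.11, SE 0.702, adjusted p = 0.0116) but varied widely within lines, and its adjusted p was 0.0516 without WFB replicate 5. OsR498G0022212200.01 lay above (log2 change 1.59, SE 0.0826, adjusted p = 6.36e-12), with at least 256 CPM on average in the first 4 hybrids, 110 ± 43.3 in WR and 59.7 to 91.7 in the parents. OsR498G0101476600.01 was also above (1.09, SE 0.120, adjusted p = 2.94e-06). Of 24748 genes 325 were above and 855 below, and 97 of these 1180 deviated by at least 2-fold. With geometric mid-parents 1637 were above and 613 below, so the prevailing direction changed with the scale. The crosses did not move together, since 309 of the 1180 genes shared a sign in 5 of 5 crosses, and the count was 3992 without WR, 3106 without RY308, 563 without RY998 and 507 without WY998. The count was 746 without RFB replicate 5, 749 without WFB replicate 5 and 771 without WFB replicate 6.

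In filling panicles OsR498G0611894900.01 (log2 change -5.28, SE 0.139, adjusted p = 4.46e-17) and OsR498G0612784300.01 (-3.57, SE 0.179, adjusted p = 1.93e-11) lay below mid-parent. The second was at 6.15 to 14.7 CPM in WY998, WY308, RY998 and RY308, 111 ± 19.6 CPM in WR (SD, n = 3) and 129 to 219 CPM in the parents. OsR498G0612770700.01 (1.30, SE 0.192, adjusted p = 0.000274) and OsR498G0100471400.01 (0.77, SE 0.139, adjusted p = 0.00217) lay above. Of 25336 genes 523 were above and 1236 below, 152 of these 1759 by at least 2-fold, and with geometric mid-parents 1260 were above and 1000 below. Of the called genes 1018 shared a sign in 5 of 5 crosses, and the count was 926 without RY998 and 950 without WY308. It was 1139 without R308 replicate 9 and RY308 replicate 8. Leaving out R998 replicate 9 raised it to 4362 and leaving out WY308 replicate 7 to 3271. It fell to 1115 without R308 replicate 7, 937 without R998 replicate 8, 908 and 757 without RFB replicates 8 and 9, and 1047 without RY308 replicate 7. It was 1019 without RY998 replicate 7, 699 and 706 without WFB replicates 7 and 8, 1103 and 1114 without WR replicates 7 and 9, and 1036 and 924 without WY998 replicates 7 and 8.

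The tissue-enriched sets were then read in the mean deviation. In young seedlings 235 of 900 seedling-enriched genes lay below mid-parent and 60 above, with a median of -0.10 on the log2 scale. For this set camera gave an adjusted p of 0.00475 with the preset correlation, and an adjusted p of 0.896 with an estimated correlation. In filling panicles 119 of 712 tested seedling-enriched genes lay below and 2 above, and of 758 tested young panicle genes 72 lay below and 6 above (camera adjusted p = 0.000139 and 0.00466, and adjusted p of at least 0.896 for both with an estimated correlation). The 1283 filling panicle genes gave 58 above and 56 below there, with a median of 0.07 and a mean of -0.01, which differ in sign (camera adjusted p = 0.00218, upward). A parental library stood apart on this set, since R998 replicate 9 had 38.6% of its counts there against 19.7% and 16.6% in R998 replicates 7 and 8, and the sets were not read without it. In WR young panicles 192 of 601 seedling-enriched genes lay below mid-parent and 9 above (camera adjusted p = 3.97e-08, and adjusted p = 0.896 with an estimated correlation). Against the mean of all young panicle libraries, WR had a median log2 level of -0.195 ± 0.117 for seedling genes (SD, n = 3). It was -0.194 ± 0.0865 for young panicle genes and -0.231 ± 0.0243 for filling panicle genes. WFB and RFB lay at 0.0953 and -0.0544 for seedling genes and 0.0313 and -0.0981 for young panicle genes. For filling panicle genes they lay at -0.106 and -0.127. WR was thus below both parents on every tissue-enriched set. Whether the seedling genes were lowered more than the other sets was not tested. By camera, no set kept an adjusted p under 0.05 in any tested contrast once the correlation was estimated. The results of fry are not given here. Choosing the sets in the parents' libraries favours lower hybrid values in the tissue where a set is high and higher hybrid values in the other tissues, so the values of a set in its own tissue are not independent of that choice.

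The 4 hybrids WY998, WY308, RY998 and RY308 form a factorial, in which WFB and RFB were each crossed to R998 and R308. The interaction asks whether exchanging R998 for R308 changed expression by the same fold in WFB crosses as in RFB crosses. It was tested on the log2 scale, where equal effects in CPM can also give a call. In young seedlings OsR498G0611586900.01 was at 38.6 ± 0.874 CPM in WY998, 20.6 ± 0.931 in WY308, 20.3 ± 1.82 in RY998 and had no count in RY308 (SD, n = 3). OsR498G0100603300.01 was at 25.6 ± 0.513, 9.29 ± 0.955, 44.0 ± 0.492 and 25.7 ± 1.36 CPM in the same order (log2 interaction 0.68, SE 0.0978, adjusted p = 0.000808). It was 1 of 20 genes called in seedlings, and the other 19 had negative values. In CPM, exchanging R998 for R308 had an effect of similar size in WFB and RFB crosses for both named genes. Additive expression could therefore give both of these calls.

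In young panicles 2581 genes showed the interaction, 1054 positive and 1527 negative. OsR498G1120000600.01 was at 1.42 ± 2.30 CPM in WY998, 12.2 ± 0.450 in WY308, 13.3 ± 0.677 in RY308 and had no count in RY998 (SD, n = 3). OsR498G0204684600.01 was at 6.21 ± 6.20, 13.5 ± 18.2 and 7.49 ± 6.76 CPM in WY998, WY308 and RY998, with no count in RY308. Its edgeR adjusted p was 0.0649 without WY308 replicate 4 and 0.0635 in a fit to the 4 hybrids alone, and that of OsR498G1120000600.01 was 0.113 in the latter. In filling panicles 5526 genes showed it, 2959 positive and 2567 negative, but 2450 were positive and 2952 negative with DESeq2 size factors, and 2505 and 2873 without block 00. There OsR498G0612408600.01 was at 15.7 ± 4.67 CPM in WY998 and 15.3 ± 2.64 in RY308, but at 0.0787 ± 0.0216 in WY308 and 0.0451 ± 0.0302 in RY998. OsR498G0101835100.01 had the opposite arrangement, with 6.47 ± 1.91 CPM in WY308, 6.05 ± 1.48 in RY998, 0.0253 ± 0.0246 in WY998 and 0.0277 ± 0.0271 in RY308. No single library left out moved the 3 interaction counts by over 1.5 times.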

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

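The tests for a mislabelled hybrid and for exchanges between crosses, for a shared state at sampling and for inheritance of R308 alleles were chosen after the results they concern had been seen. Block 06 and the genes marking R308 were picked after looking over the blocks, and over the 4 parents in 3 tissues.

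The deviation of hybrids from mid-parent differed between tissues, by a test of the difference itself. Young panicles differed from young seedlings in 2206 genes (1232 higher, 974 lower), filling panicles from young seedlings in 5123 (1998 higher, 3125 lower) and filling from young panicles in 1097 (323 higher, 774 lower), of 27316 genes tested. The interaction, in which the log2 effect of R998 against R308 differed between WFB and RFB crosses, was called for 20 genes in young seedlings, 2581 in young panicles and 5526 in filling panicles.

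The panicle interaction was weighed first. For a mislabelled hybrid, the lowest median level of genes present in 1 parent, in a hybrid carrying it, was 0.248, but this rests on 1 gene of WFB and decides nothing. An exchange between crosses with R998 and with R308 is argued against by genes of these parents, with a lowest value of 0.351 in hybrids carrying the parent and at most 0.0138 in the others. With a limit of 20 CPM in the parent, the highest value in the others was 0.182, in WY998 replicate 6 over 2 genes of R308. An exchange between crosses with WFB and with RFB is argued against by 83 genes that differed between these parents with the same sign in all 3 tissues. By their median, each of the 24 panicle libraries lay on its own side of the middle of both crosses, by at least 0.236 on the log2 scale. A single library is argued against by the filling panicle count, which was still 4535 without the library of most effect. Lines sampled at different points between young and filling panicles would make the interaction follow the change between those stages. The correlation across genes was 0.060 in young panicles and 0.063 in filling panicles, under the limit of 0.1 set beforehand for arguing against this. That limit was set over all genes, which was the wrong set, since only 2578 of 24625 and 5519 of 25108 genes were called and the rest dilute the value. Over the called genes it was 0.161 and 0.145, and by rank over all genes 0.105 and 0.102, so this stays open. Over 36 genes marking R308 in filling panicles alone, RY998, which has no R308 parent, lay at 0.615 of the way to R308 and RY308, which has it, at 0.119. For these 36 genes this argues against inheritance of R308 alleles and would fit a state at sampling that WY308 (0.744), RY998 and R308 may have shared in filling panicles. In the same libraries, 97 genes marking R308 in every tissue followed the crosses (RY308 0.437, WY308 0.575, RY998 0.004, WY998 -0.006). In young panicles, 31 genes marking R308 there alone put WY308 at 0.817, WY998 at 0.580, RY998 at 0.503 and RY308 at 0.287. WY308 and RY998 again lay nearer R308 than RY308 did. WY998, at -0.035 over the 36 filling panicle genes, now lay with them. Whether a state at sampling was shared in young panicles too was not tested. There 22 genes marking WFB alone also ran against the crosses, with RY308, which has no WFB parent, at 0.749 and WY998 and WY308 at -0.036 and 0.114. Genes marking R998 in 1 panicle stage alone went with the crosses. In filling panicles 25 of them put WY998, RY998, WY308 and RY308 at 0.377, 0.505, 0.015 and 0.016. In young panicles 38 put them at 0.316, 0.344, 0.141 and -0.033. In young panicles 17 genes marking RFB alone put RY308 and RY998 at 0.471 and 0.095, and WY998 and WY308 at -0.159 and -0.347. The 13 genes marking WFB in every tissue lay at 0.529 to 0.647 in young panicles of all 4 hybrids and do not separate the crosses. In filling panicles 12 such genes put RY998 and RY308 at 0.524 and 0.587, and WY998 and WY308 at 0.629 and 0.502. In young seedlings 15 genes marking RFB in every tissue put WY998 and WY308, which have no RFB parent, at 0.515 and 0.520. RY998 and RY308 lay there at 0.530 and 0.585. In filling panicles 8 such RFB genes went with the crosses. They put RY998 and RY308 at 0.288 and 0.434, and WY998 and WY308 at 0.001 and 0.058. The cause was not tested. An interplay of parental alleles stays open and untested.

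Weighed next was the concentration of differences between WFB and RFB in block 06. In hybrids that differ in carrying WFB or RFB, at least 97.9% of the called block 06 genes kept the parental sign in young seedlings, but elsewhere 92.5% and 90.1% did, so this is not special to the block. In young panicles 85.2% of the block 06 genes kept it in crosses with R998 and 77.2% in crosses with R308, where 38 were called in the opposite direction, and in filling panicles 88.6% and 97.7% did. Of the called block 06 genes 82.3% had another called gene among the 5 tested genes on either side, above all 1000 random draws (highest 69.5%). Blocks 01, 02, 03 and 07 also exceeded all their draws in young seedlings (51.0%, 43.8%, 36.1% and 59.3%), so grouping is not special to block 06. The draws did not allow for neighbouring genes that change together or share reads, so the grouping cannot decide against a shift of stage or condition. A candidate explanation is segments that differ between the lines, which were not tested with sequence. A single stretch would not cover them, since in young seedlings, of 10 equal parts of the block in identifier order, parts 1 and 2 had 12.7% and 25% of their genes called, parts 7, 9 and 10 had 9.39% to 11.6%, and the others at most 3.33%. In young panicles the neighbour share of 96.6% was reached by 356 of 1000 draws.

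Libraries were also reassigned to the groups compared. The reassigned groups mixed libraries of different lines, which can widen the spread within groups and lower the counts by itself. A higher real count therefore points at most to differences between lines and does not exclude chance for a given result. The smallest possible share was 1 of 21, and no allowance was made for the number of results. In young seedlings the real assignment gave 2077 calls beyond both parents, 4264 for the mean deviation and 20 for the interaction. The others gave at most 0, 0 and 5. The real assignment also gave the most in filling panicles, with 1817 (highest other 0), 1759 (highest other 0) and 5526 (highest other 954) in the same order. So it did in young panicles for calls beyond both parents (2887, highest other 0). In young panicles 2 of 21 assignments gave as many genes for the mean deviation (1180, highest other 1814) and for the interaction (2581, highest other 4053).

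For single hybrids against mid-parent, the real assignment gave the most genes in young seedlings for RY998 (916, highest other 442), RY308 (518, highest other 1) and WR (3324, highest other 16). The same held in young panicles for WY998 (3381, highest other 2436), RY998 (6028, highest other 930), RY308 (3792, highest other 61) and WR (5309, highest other 4644), and in filling panicles for RY998 (3216, highest other 1696), RY308 (1557, highest other 35) and WR (291, highest other 12). The WR count in filling panicles fell to 2 without WR replicate 9, so it depends on single libraries. Chance cannot be excluded for WY998 in young seedlings (61, highest other 1510), WY308 in young panicles (1331, highest other 4132) and WY308 in filling panicles (1648, highest other 3586), where 3 of 21 assignments gave as many. Nor can it for WY308 in young seedlings (187, highest other 473) and WY998 in filling panicles (36, highest other 89), with 2 of 21. A reassignment can put parental libraries in the place of the hybrid, so that the difference between the parents itself appears as a deviation. Other assignments that called several times the real count, as for WY998 in young seedlings, therefore do not decide about chance.

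Parents, with 3 libraries against 3, have 10 splits, too few for a share under 0.05. In young seedlings the real split and the highest other gave 4532 and 5 genes for WFB and R998, 4385 and 0 for WFB and R308, 4331 and 3 for RFB and R998, 4129 and 0 for RFB and R308, and 393 and 0 for WFB and RFB. In young panicles they gave 10827 and 0, 9077 and 0, 10347 and 1, 12267 and 0, and 5330 and 1 in the same order, and in filling panicles 5404 and 0, 8651 and 0, 5260 and 1465, 7210 and 0, and 180 and 0. For tissues, only the real 1 of 21 assignments gave as many genes, and there the reassigned groups mixed tissues. The real and highest other counts were 23525 and 2 for young panicles against young seedlings, 23695 and 4282 for filling panicles against young seedlings, and 23513 and 3 between the panicle stages.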

How the results depend on the processing

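Leaving out block 00 and leaving out both R308 replicate 9 and RY308 replicate 8 were chosen after seeing the data, and the other alternatives were planned. No named gene changed direction under any of them, but the more frequent direction within a count did, in 13 of 18 counts with the geometric mid-parent, 11 of 42 with DESeq2 size factors and 10 of 42 without block 00. A geometric mid-parent lies below the arithmetic one wherever the parents differ, and for the other settings the cause was not tested. Where a count moved by over 1.5 times, the cause was not tested. For named genes, 1458 of 1503 values kept their direction and their side of the threshold, and 45, from 11 of 90 genes and comparisons, kept the direction with an adjusted p above 0.05. Of these 36 came from leaving out 1 library and 5 from fitting only the lines compared. OsR498G0204684600.01 lost significance with a replicate block (0.0616), and OsR498G0407779200.01 with DESeq2 size factors (0.0506), without R308 replicate 9 and RY308 replicate 8 (0.0736) and without block 00 (0.0504). The gene lists and cell type markers drawn up beforehand could not be matched to the identifiers, so nothing is given for them. How the counts depend on depth was not tested. A group with no count gives only a bound on a fold, and a group with 1 to 3 counts a ratio with a wide counting interval.

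On average, replicate numbers did not pair the libraries. Deviations of libraries with the same number correlated at -0.006 in young seedlings, -0.011 in young panicles and -0.034 in filling panicles on average, and 6, 8 and 10 of 27 libraries matched their own number best. Single pairs with the same number ran from -0.523 to 0.612, -0.592 to 0.559 and -0.713 to 0.719 in the same order. In young panicles WY998 replicate 5 and RY998 replicate 5 had the same highest correlation with another line, 0.993. Replicate 4 of these lines did so too, at 0.989. Pairing of some libraries is therefore not excluded. With the number as a replicate block, WR in filling panicles gave 172 genes, and the other 38 counts stayed within 1.5 times.

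Requiring a 2-fold change left 14332 genes for young panicles against young seedlings, 13980 for filling panicles against young seedlings and 11297 between the panicle stages. DESeq2 gave 204 for WY998, 457 for WY308, 903 for RY308, 33 for the interaction and 591 for WFB against RFB in young seedlings, and 168 for WY998, 1059 for WR and 2726 for the mean deviation in filling panicles. The geometric mid-parent gave 933 for WY998, 1008 for WY308, 2029 for RY998 and 1376 for RY308 in young seedlings, 2274 for WY308 and 2250 for the mean in young panicles, and 691 for WY998 in filling panicles. Without a filter on low counts, WR gave 83 and the mean 1097 in filling panicles. Fits to the compared lines alone gave 16 for WY998, 361 for WY308, 2208 for WR and 2986 for WFB against R998 in young seedlings, and 1647 for the interaction in young panicles. In filling panicles they gave 13 for WY998, 218 for WY308, 3551 for WR, 2988 for RFB against R998 and 2983 for WFB against R998. Without R308 replicate 9 and RY308 replicate 8, filling panicles gave 826 for RY308, 171 for WR, 935 for WY308 and 1139 for the mean. Adjusting the larger of both p-values gave 1301 calls beyond both parents in young panicles. The same sign in 5 of 5 crosses left 309 genes of the mean in young panicles and 1018 in filling panicles. The mean was 2797 without WR in young seedlings. In young panicles it was 3106 without RY308, 563 without RY998, 3992 without WR and 507 without WY998, and in filling panicles 926 without RY998 and 950 without WY308. DESeq2 size factors moved the median log2 difference of filling panicles from young seedlings by 0.10, and no filter moved it to 0.49.

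Leaving out 1 library at a time gave these lowest and highest counts. Against mid-parent in young seedlings they were 26 and 115 for WY998, 47 and 192 for WY308, 360 and 1475 for RY998, 160 and 467 for RY308, and 2135 and 3045 for WR. Young panicles gave 1767 and 3287 for WY998, 735 and 1222 for WY308, 2843 and 6271 for RY998, 2249 and 3768 for RY308, and 2033 and 6131 for WR. Filling panicles gave 15 and 86, 599 and 2708, 1857 and 3917, 622 and 1686, and 2 and 185 in the same order. Beyond both parents the range was 1366 to 2429 in young seedlings, 1679 to 3457 in young panicles and 1261 to 2154 in filling panicles. The mean deviation ranged from 3360 to 5070, 746 to 1372 and 699 to 4362 in the 3 tissues, and the interaction from 18 to 23, 1903 to 3179 and 4535 to 5418. Between parents, young seedlings ranged from 3678 to 4421 for WFB and R998, 3331 to 4277 for WFB and R308, 3314 to 4491 for RFB and R998, 2960 to 4314 for RFB and R308, and 258 to 411 for WFB and RFB. Young panicles ranged from 8905 to 10327, 7509 to 8049, 8522 to 9910, 10323 to 11813 and 3015 to 5473, and filling panicles from 3718 to 6660, 6390 to 8250, 3683 to 7289, 5567 to 6905 and 124 to 144. Where this leaves a line with 2 libraries, the spread is taken from all lines. Tissue counts without each line stayed within 1.5 times.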

Other observations

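Genes separating the 4 factorial hybrids from the other lines were looked for after OsR498G0611894900.01 had been seen, and the comparisons with WR were chosen after that result too. The crosses with no parent in common, the sign of the parental difference outside block 06 and the filling panicle transcripts in a young panicle library were also read after the results were seen.

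In all 3 tissues, 8 genes set WY998, WY308, RY998 and RY308 apart from every parent and from WR, with 2 above and 6 below. OsR498G0612784300.01 was at 53.9 ± 14.4 CPM in the 12 seedling libraries of these hybrids (SD, n = 12) and at 1381 ± 440 CPM in those of the parents. OsR498G0611897500.01 was at 1.69 ± 0.626 against 15.5 ± 4.11 CPM, OsR498G0611897700.01 at 16.4 ± 5.31 against 36.5 ± 4.91 CPM, and OsR498G0611899800.01 at 1.29 ± 0.213 against 2.99 ± 0.484 CPM in the same libraries. With OsR498G0611894900.01 these make 5 genes in block 06, and 3 further genes are in block 00. The block 00 genes, among them both genes above, had mean levels under the naming limit of 5 CPM in every tissue. In seedlings OsR498G0022205200.01 was at 1.04 ± 0.277 CPM in these hybrids, with no count in the parents. OsR498G0022210100.01 was at 0.406 ± 0.137 against 0.0154 ± 0.0210 CPM. OsR498G0022226800.01 had no count in these hybrids and 0.733 ± 0.160 CPM in the parents. Among all choices of 4 of the 9 lines, 1 gave as many as 8 genes, namely the real one, and the highest other gave 3. Chosen as apart from the parents alone, with WR not used, the same 8 genes came out, so the choice did not fix the level of WR. WR is a hybrid as well, but its median shift in the direction of the other 4 hybrids was 0.227% of theirs over the 3 tissues. This argues against an effect that every hybrid would show alike. The parents of WR differed in fewer genes than those of the other crosses. An effect that grows with the difference between the parents could be small in WR and stays open. By tissue it was 0.918% in young seedlings, -5.71% in young panicles and 10.6% in filling panicles, and at most 16.6% in a single replicate of WR in 1 tissue. In filling panicles 7 of the 8 genes moved in the direction of the other hybrids, OsR498G0611897700.01 the most at 31.5% of their shift, so a small part in that tissue stays open. Also open, and not tested, is something that these 4 hybrids may share and the other lines lack, such as the origin of the seed.

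Hybrids with no parent in common were compared across genes, which are not independent replicates. In young panicles WY998 and RY308 deviated from mid-parent with a correlation of -0.157, and 1181 genes were called in opposite directions. In the other tissues they agreed, with correlations of 0.349 in young seedlings, where no gene was called in opposite directions, and 0.375 in filling panicles, where 1 was. WY308 and RY998 correlated at 0.483 in young seedlings and at 0.371 in young panicles, where 505 genes were above mid-parent in both (88.2 from independent lists) and 393 below in both (74.2 from independent lists). In filling panicles they correlated at 0.390, with 397 genes above in both (34.0 from independent lists) and 559 below (74.5 from independent lists). Mean deviations in filling and young panicles shared 27 genes above (6.66 from independent lists) and 177 below (40.1 from independent lists), with 10 and 6 genes opposite. The overlaps with young seedlings were weaker. Genes above in a panicle stage were called below in seedlings more often than above in both. Opposite calls were not set against independent lists. Filling panicles and young seedlings shared 36 above (41.4 from independent lists) and 172 below (117 from independent lists), with 88 and 164 opposite, and young panicles and young seedlings 42 above (26.9 from independent lists) and 117 below (77.2 from independent lists), with 54 and 79 opposite. These comparisons share no libraries. The deviation of WR from its parents, set against the mean of the other 4 hybrids with the libraries of WFB and RFB divided between both, correlated at 0.498 to 0.591 in young seedlings, -0.462 to -0.246 in young panicles and 0.286 to 0.398 in filling panicles.

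The young panicle library RY308 replicate 4 held OsR498G0102044500.01, OsR498G0713719900.01 and OsR498G0306248900.01 at 47.9, 28.1 and 16.4 CPM. Its share of counts on the filling-panicle-enriched set was 0.264%, below the highest of the other young panicle libraries, 0.365%. Tests of the large seedling count of WR were set out and then withdrawn when the genes above came into view, so no explanation of its 3324 genes was weighed.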
